A study of Ovis aries with 16 samples.

How the data were processed

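Left ventricular tissue of fetal sheep was hybridized to a 1-colour Agilent sheep array (red channel), 1 array per fetus, on 2 slides of 8 arrays, each slide with 1 scan. The labels give the 8 twin sets, and in each 1 fetus was treated and the other was not. They describe the infusions both as daily and as continuous, and the tissue both as the free wall and as the free wall with the septum, and these differences could not be settled. RNA integrity numbers were 7.5 to 10 over the study, per the labels. Arrays are named here by twin set, since the numbers in the sample titles do not follow the twin sets.

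The deposited scanner files hold spot intensity values in fluorescence units that Agilent Feature Extraction 10.7.3.1 had background-subtracted and detrended across the array, with low values replaced by surrogates and no normalization between arrays, per the file headers. The deposited value table of the series holds values close to the natural log of the mean spot signal (r of at least 0.9978 on each array, slopes of 1.018 to 1.056). Its column medians are 5.755 to 5.768, and the method that made it is not given in the sources used here. In that table the slide means of a probe differed by a median of 0.0303 on the log2 scale, against 0.130 in the normexp values of the same arrays, so slide differences are smaller in it. It served only as an alternative. Whether its slide differences had been adjusted away in part is not recorded, so the counts from its fits call for caution.

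Each array held 15744 spots, of which 15208 were not controls and stood for 15008 probes. Outlier spots marked by the scanner software (3 to 9 per array) and control spots were left out, and spots of 1 probe were averaged. No probe was saturated. The median coefficient of variation of replicate spots was 7.8% to 11.6%, the slope of the spike-in signals was 0.96 to 0.998, and arrays correlated with each other at 0.951 to 0.992 over 120 pairs. Values were the log2 processed signal minus the 75th percentile of its array. A probe was tested where it was well above background on every array of at least 1 of the 4 groups, which left 8970 probes.

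Gene names came from the reference gene table (assembly ARS-UI_Ramb_v3.0) by accession (722 probes), symbol (497), gene identifier (134), synonym (20), description (231) or sequence cluster (72). A further 127 probes kept the name in the files. In all 1803 probes had a name and 13205 had none. A gene was represented by its probe with the highest mean log2 value over the 16 arrays among tested probes; 254 of the 564 tested genes had several. Of the 11 such genes with any probe past the threshold with losartan, all probes passed in 7, and signs differed in 0.

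The comparisons were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) on all 16 arrays, with the 8 twin sets as fixed block terms and 1 term per treatment, which left 6 residual degrees of freedom (prior degrees of freedom 3.68). Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The untreated twins of the 2 arms were compared over their 8 arrays with no block. Gene lists, 29 in all, were tested with camera in limma at a preset correlation of 0.01 where at least 5 genes were measured (17 lists; 12 were below this). HMMR, which lacked a value in twin set 6, was left out of camera, leaving 563 genes. With an estimated correlation no list passed in any comparison. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.

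The pairing comes from the labels, which state the twin sets. Deviations from the group means correlated at 0.22, 0.24, 0.46, 0.08, -0.04, 0.28, 0.15 and 0.53 in twin sets 1 to 8 (mean 0.24), against a mean of 0.10 for other pairs on the same slide and -0.25 for pairs on different slides. The twins of sets 2, 3, 6 and 8 shared a slide. Other pairs include arrays of 1 group, whose deviations from their shared mean are pulled towards a negative correlation, while twins are never in 1 group. The comparison can therefore overstate how alike twins were.

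Groups, comparisons, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the alternatives without twin sets 2, 7 and 8 and with slide and array row together as blocks, which were chosen after seeing the data. The genes named were, per treatment, up to 10 with the largest rise and 10 with the largest fall among those past the threshold with the same sign in all 4 twin sets, filled up to 5 by smallest unadjusted p and then named as not passing. Added to these were up to 4 members of each list with the smallest unadjusted p, the measured members of the renin-angiotensin list with NPPA, NPPB, MYH6, MYH7 and ACTA1, and the 5 genes with the largest difference of the effects each way among those past the threshold. Some of the list members that this rule selects are left out of the text. Probes without a name were counted and not named. A withheld item is not reported here. A probe not well above background on any array of a group has only a bound there. The fold is then the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

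The steps were tested on simulated data of 8965 probes, of which 8765 had no change. For losartan 34.3% of the 67 probes changed by 0.5 on the log2 scale were recovered, 77.6% of 67 at 1 and 100% of 66 at 2; for angiotensin II the shares of as many probes were 35.8%, 86.6% and 98.5%. Among the 8765 unchanged probes 11 were called for losartan and 6 for angiotensin II. The simulated noise was independent between probes and held no slide effect and no arrays that stood apart. These shares may therefore not hold for the real data. Alternatives covered the scaling of arrays, background correction, source of the values, filter on dim probes, block, slide, array row, array weights, variance prior, threshold, set test and twin sets left out in turn.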

Results

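Gene expression was measured in the left ventricle of 16 fetal sheep from 8 twin pairs, 5 days into treatment in utero. Catheters were placed at 125 to 126 days of a 145-day gestation. In twin sets 1 to 4, 1 fetus of each pair received losartan, an antagonist of the type 1 angiotensin II receptor (AT1). In twin sets 5 to 8, 1 fetus of each pair received angiotensin II, the effector peptide of the renin-angiotensin system. The other fetus of each pair was untreated, so the design compared each treatment with untreated twins and asked how angiotensin II, acting through AT1 or blocked there, regulates genes of the late-gestation heart. Each fetus was assayed on 1 array, giving 4 arrays in each of 4 groups, and this number limited the precision. The 75th percentile of the processed signal ranged from 1099 to 1670 fluorescence units, and 8601 to 9615 of the 15008 probes (57.3% to 64.1%) were well above background on an array. Of the 8970 probes tested, 864 carried a gene name, and these stood for 564 genes.

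The first principal component (32.1% of the variance) set 3 arrays apart from the rest. They were the untreated twin of set 2 (score 39.8) and the angiotensin II fetuses of set 7 (37.4) and set 8 (30.1), while the other 13 arrays scored between -19.0 and -0.4. All 3 lay on slide 2 in the same array row. The control corner spots, which report on hybridization and carry no sheep sequence, had log2 signals of 16.91 to 17.47 on these 3 arrays and 14.30 to 15.17 on the others. The losartan arm was spread unevenly over the slides, with 1 treated and 3 untreated fetuses on slide 1 and 3 treated and 1 untreated on slide 2. The angiotensin II arm had 2 of each on each slide. Scores on the second principal component (19.9% of the variance) were mostly negative on slide 1 and mostly positive on slide 2. On it the losartan fetuses of sets 1 to 4 scored 9.2, 16.1, 8.0 and 26.8. Their untreated twins scored -10.5, 3.7, -11.3 and -6.9. Slide and losartan treatment thus overlap on this component.

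**Figure D1:**
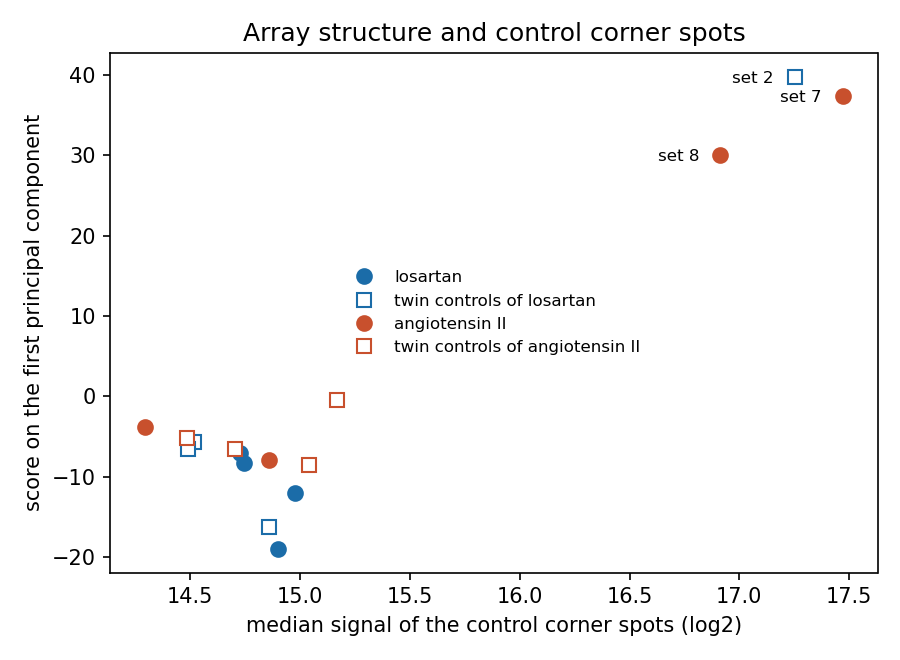
Score of each of the 16 arrays on the first principal component against the median log2 signal of its control corner spots; filled circles are treated and open squares untreated fetuses, with the losartan arm in blue and the angiotensin II arm in red. The untreated twin of set 2 and the angiotensin II fetuses of sets 7 and 8 scored 30.1 to 39.8, and the other 13 arrays scored -0.4 or less.

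Genes that drive cell division had lower signals in the losartan fetuses than in their untreated twins. CCNB1, the cyclin of entry into mitosis, fell by 2.19 on the log2 scale (SE 0.30, adjusted p = 0.00855, limma), and CDK1, its kinase partner, fell by 2.07 (SE 0.22, adjusted p = 0.00239, limma). CCNA2, the cyclin of S phase and G2, fell by 1.88 (SE 0.22, adjusted p = 0.00431, limma), and TYMS, which makes the thymidylate needed for DNA synthesis, fell by 1.82 (SE 0.20, adjusted p = 0.00286, limma). HMMR, a protein of the mitotic spindle, fell by 1.54, and PCNA, the sliding clamp of DNA replication, fell by 0.73. Each of these 6 genes was lower in the losartan fetus than in its twin in 4 of 4 twin sets. They were 6 of the 13 measured members of a fixed cell cycle list, of which 12 had estimates below 0 and 9 passed when adjusted over the list alone. The list fell relative to the other genes (median log2 change -1.08, camera adjusted p = 6.89e-08 over 17 lists; adjusted p = 0.145 with an estimated correlation), with medians of -0.79, -0.81, -0.62 and -1.40 in twin sets 1 to 4. With the slide as a further block the list passed (camera adjusted p = 6.62e-06; adjusted p = 0.256 with an estimated correlation). In fits within a slide, which had no twin block and set 1 losartan array against 3 untreated on slide 1 and 3 against 1 on slide 2, the camera adjusted p was 1.87e-07 and 0.190, with the lone array assumed to vary like the others. CDK1 was well above background on 2 of the 4 losartan arrays and CCNA2 on 1 of the 4, and their changes were -1.33 and -1.15 in the authors' value table.

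**Figure D2:**
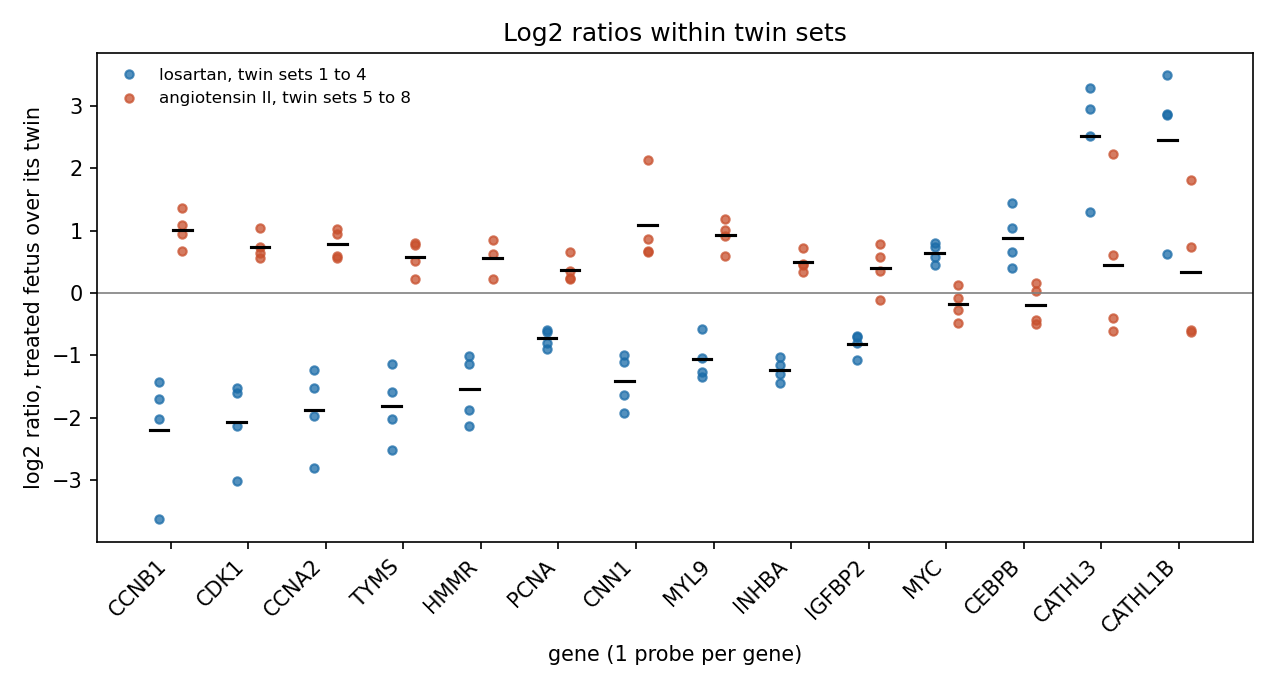
Log2 ratio of the treated fetus over its untreated twin for 14 genes (vertical axis, log2), with 1 point per twin set, losartan in blue and angiotensin II in red, and a black bar at the mean. All points of the cell cycle genes CCNB1, CDK1, CCNA2, TYMS, HMMR and PCNA lie below 0 with losartan and above 0 with angiotensin II. With angiotensin II no gene passed over all tested probes, and HMMR has 3 points.

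Several genes outside the cell cycle list also fell with losartan. ASPM, a spindle pole protein, and PMCH, the precursor of melanin-concentrating hormone, were well above background in 4 of 4 untreated twins and in 0 of 4 losartan fetuses. PMCH was at least 2.97-fold lower (mean -1.99 ± 0.32 in the twins against a measured -4.50 ± 0.89 on the normalized log2 scale, SD, n = 4; adjusted p = 0.0112, limma) and ASPM at least 1.85-fold lower (adjusted p = 0.0455, limma). INHBA, which encodes the subunit of activin A, fell by 1.23 (SE 0.11, adjusted p = 0.00142, limma), and both of its probes passed. Of 3 measured smooth muscle genes, CNN1 (calponin) fell by 1.42 (SE 0.25, adjusted p = 0.0249, limma) and MYL9 (myosin regulatory light chain) by 1.06 (SE 0.14, adjusted p = 0.00855, limma), while MYLK, the myosin light chain kinase, had an estimate of -0.36 that did not pass. SQLE, an enzyme of cholesterol synthesis, fell by 0.87, IGFBP2, a binding protein of insulin-like growth factors, by 0.82 and JUND, a transcription factor of the AP-1 family, by 0.62 (limma adjusted p from 0.0261 to 0.0482). These calls depended on the processing: SQLE passed in 5 of 22 alternatives, with estimates of -1.21 to -0.16, JUND in 5 of 21, IGFBP2 in 9 of 22 and ASPM in 7 of 21. CNN1 passed in 13 of 22 (-1.56 to -1.16), MYL9 in 16 of 22 (-1.33 to -0.67) and INHBA in 18 of 22 (-1.30 to -0.70). PMCH passed in 15 of 21. Each gene named here as having fallen was lower in 4 of 4 twin sets.

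Genes of the extracellular matrix fell as a group with losartan, by less than the cell cycle genes. Of 17 measured members of the fibroblast and matrix list, 16 had estimates below 0 (median log2 change -0.33, camera adjusted p = 0.00124; adjusted p = 0.335 with an estimated correlation). None passed over all tested probes, and 4 passed when adjusted over the list alone. The members with the smallest p were the protease inhibitor TIMP1 (-0.45, adjusted p = 0.0518, limma), the matricellular growth factor CCN2 (-0.90, adjusted p = 0.0712, limma), the collagen COL12A1 (-1.08, adjusted p = 0.0913, limma) and TGFB2 (-1.13, adjusted p = 0.222, limma), all lower in 4 of 4 twin sets. The list median was -0.63 in twin set 2, whose untreated twin stood apart in the array structure, and -0.15, -0.27 and -0.37 in sets 1, 3 and 4. In the fit within slide 1, which had no twin block and a single losartan array, the list did not pass (camera adjusted p = 0.0732); within slide 2, with a single untreated twin, it did (0.00161).

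Among named genes past the threshold, the largest rises with losartan were those of 2 cathelicidins, antimicrobial peptides stored by neutrophils. CATHL3 rose by 2.52 on the log2 scale, or 5.74-fold (SE 0.44, adjusted p = 0.0261, limma), and CATHL1B by 2.46, or 5.52-fold (SE 0.49, adjusted p = 0.0482, limma), each higher in 4 of 4 twin sets. The other tested probe of CATHL1B had an estimate of 2.41 and did not pass (adjusted p = 0.0638, limma). CATHL1B passed in 5 of 22 alternatives, with estimates of 2.06 to 3.08, the highest without twin set 2, where its log2 ratio was 0.62. CATHL3 passed in 13 of 22, with estimates of 2.24 to 2.93. With the slide as a further block CATHL3 did not pass (2.24). BAC5, another cathelicidin, chosen after its values were seen, had an estimate of 2.23 and did not pass (adjusted p = 0.116, limma). With angiotensin II the estimates of CATHL3, CATHL1B and BAC5 were 0.46, 0.33 and 0.45, with log2 ratios of 2.23, 1.81 and 1.86 in twin set 6, and their differences between the treatments did not pass (limma adjusted p = 0.132, 0.147 and 0.233). Of the 8 measured macrophage and leukocyte markers, 2 had estimates above 0 and none passed (median log2 change -0.12, camera adjusted p = 0.962). HBB, a beta globin and the single erythroid marker measured, had an estimate of 1.15 (SE 0.52, adjusted p = 0.413, limma) and was higher in 3 of 4 twin sets. Transcription factors MYC (0.65, adjusted p = 0.0323, limma) and CEBPB (0.89, adjusted p = 0.0491, limma) also rose in 4 of 4 twin sets; CEBPB was well above background in 2 of the 4 untreated twins. CEBPB passed in only 2 of 21 alternatives and MYC in 8 of 22. LPL, the lipase that frees fatty acids from lipoproteins, did not pass (0.65, adjusted p = 0.0811, limma).

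Over all tested probes, 109 of 8970 passed with losartan in limma at an adjusted p under 0.05, of which 20 rose and 89 fell (81.7%). In the authors' deposited values 434 passed, of which 181 rose and 253 fell (58.3%), and 102 of the 109 were among them. The median absolute log2 change of the 109 was 1.11. The 28 probes with a gene name stood for 21 names, and 81 passing probes had none. The other 15 of the 17 lists tested did not pass with losartan (camera adjusted p from 0.185 to 0.962), among them the 6 interferon-stimulated genes, all with estimates below 0, the 23 cytosolic ribosomal proteins (median log2 change 0.00) and the 7 genes of oxidative phosphorylation (0.04). Leaving out twin set 1, 3 or 4 lowered the 109 probes to 64, 33 or 49, and without the twin set as a block 0 passed. With the slide as a further block 71 passed, 58 of them among the 109; fits within a slide had no twin block, and there 42 passed on slide 1 (35 shared), with a single losartan array, and 546 on slide 2 (1 shared), where the single untreated twin was the array that stood apart.

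**Figure D3:**
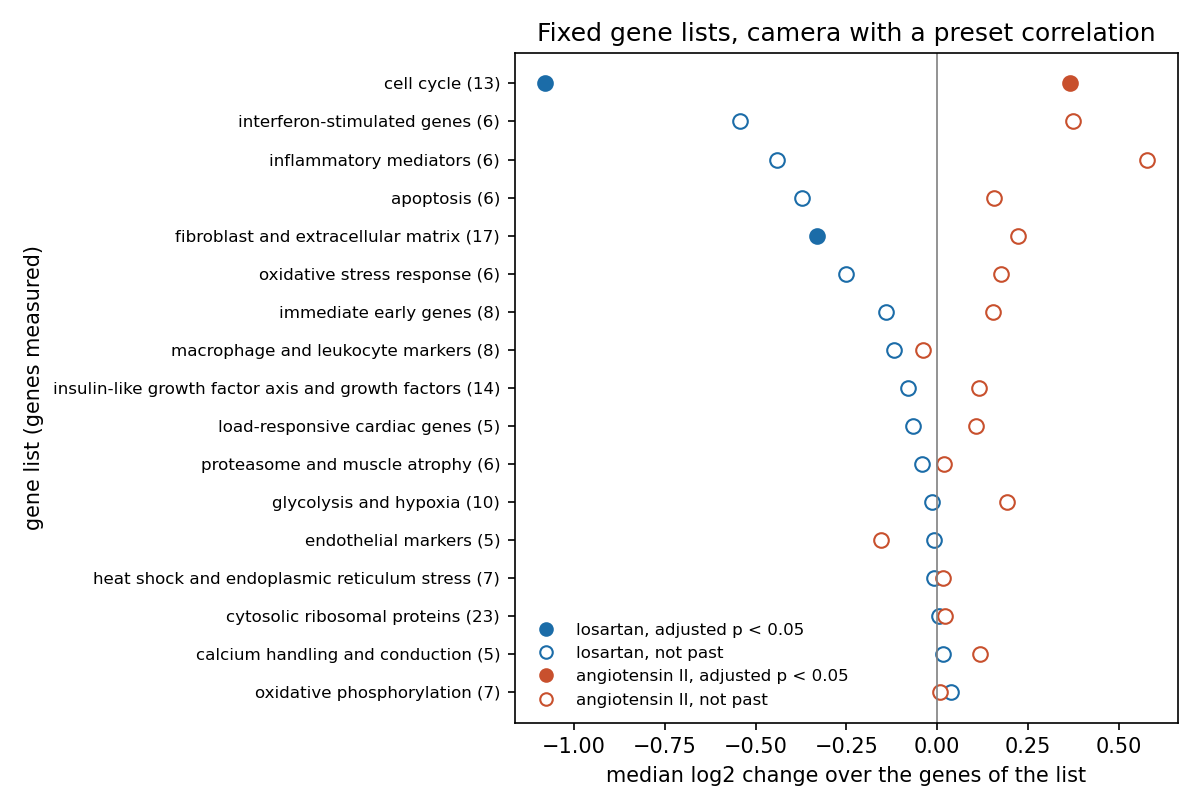
Median log2 change of each of the 17 fixed gene lists with at least 5 measured genes, with losartan in blue and angiotensin II in red; filled points passed camera with a preset correlation at an adjusted p under 0.05, and the number of genes measured is in brackets. The cell cycle list lies at -1.08 with losartan and 0.37 with angiotensin II, and the fibroblast and extracellular matrix list at -0.33 and 0.22.

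With angiotensin II the cell cycle list rose in camera with a preset correlation, with no single gene past the threshold. Of the 13 measured members, 12 had estimates above 0 (median log2 change 0.37, camera adjusted p = 0.00135; adjusted p = 0.366 with an estimated correlation and 0.0708 in fry), and 5 passed when adjusted over the list alone. CCNB1 had an estimate of 1.02 (SE 0.30), CCNA2 of 0.78 (SE 0.22), CDK1 of 0.75 (SE 0.22) and PCNA of 0.37 (SE 0.11), each higher in 4 of 4 twin sets and none past the threshold (limma adjusted p of 0.457 to 0.458). The list median was 0.23, 0.36, 0.64 and 0.34 in twin sets 5 to 8. With the slide as a further block the list passed (camera adjusted p = 0.00338; adjusted p = 0.683 with an estimated correlation). In fits within a slide, with no twin block and 2 arrays per group, the camera adjusted p was 1.83e-04 on slide 1 and 0.347 on slide 2.

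No single gene passed over all tested probes under angiotensin II. MYL9, INHBA and CNN1, which fell with losartan, were among the 5 genes with the smallest p on the higher side. MYL9 had an estimate of 0.93 (SE 0.14) and INHBA of 0.50 (SE 0.11), both higher in 4 of 4 twin sets (limma adjusted p = 0.427 and 0.439). CNN1 had an estimate of 1.09 (SE 0.25), with 2.13 in twin set 6. BAMBI, a decoy receptor of the transforming growth factor family (0.59), and LOC100101238, a chemokine named regakine 1-like (0.94), were the others. On the lower side stood the growth factor FGF1 (-0.45), the NADPH oxidase NOX5 (-0.52), CPT1B, which admits long-chain fatty acids to mitochondria (-0.34), the cytokine IL3 (-0.59) and LEP, which encodes leptin (-0.40), each lower in 4 of 4 twin sets with limma adjusted p of 0.457 to 0.458. BAMBI and LOC100101238 were higher in 4 of 4.

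In limma 0 of 8970 probes passed with angiotensin II (smallest adjusted p = 0.427), while 938 had an unadjusted p under 0.05 against 448 expected by chance. Counted over named genes alone, 1 passed, MYL9, which had the smallest p of the named genes. In fits within a slide, without the twin block, 353 probes passed on slide 2, where both angiotensin II arrays were among the 3 that stood apart, and 0 on slide 1; with the twin block and the slide as a further block 0 did. Of the gene lists, only that of the cell cycle passed in camera, and the matrix list did not (12 of 17 estimates above 0, median 0.22, camera adjusted p = 0.501). Without twin sets 2, 7 and 8 the matrix list had 8 of 17 estimates above 0 (median -0.0043, camera adjusted p = 0.645), while with the mean of all probes of a gene it passed (0.0497). The matrix regulators TIMP3 (0.92), CCN2 (0.59) and TGFB2 (0.76) and the collagen COL3A1 (-0.38) had the smallest p of that list, and none passed in limma; without twin sets 2, 7 and 8 the estimate of TIMP3 was 0.41 and that of TGFB2 0.15. The other 4 probes of COL3A1 had estimates of -0.02 to 0.31. The 6 measured inflammatory mediators all had estimates above 0 (median 0.58, camera adjusted p = 0.0577). They passed with the slide as a further block (camera adjusted p = 0.0466) and, as the only list, in fry (adjusted p = 0.0177). With an estimated correlation the mediators did not pass (camera adjusted p = 0.366), and over the alternatives their adjusted p was 0.00453 to 0.417. Their largest estimate was that of CXCL1, a neutrophil chemoattractant (1.64, SE 0.79), which was 3.60 and 3.28 in twin sets 7 and 8, whose angiotensin II arrays stood apart, and -0.29 and -0.04 in sets 5 and 6. Leaving out twin set 2, 7 or 8 gave 2, 3 or 2 lists past the threshold in place of 1.

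The receptors and other measured members of the renin-angiotensin system did not pass in either arm. AGTR1, the AT1 receptor, had log2 estimates of 0.00 with angiotensin II and -0.08 with losartan (SE 0.26 in both). AGTR2, the type 2 receptor, had estimates of -0.49, lower in 4 of 4 twin sets, and 0.23 (SE 0.21; limma adjusted p = 0.467 and 0.697). NR3C2, the mineralocorticoid receptor, had estimates of 0.21 and -0.07 (limma adjusted p = 0.552 and 0.886). The 4 probes for ACE, the angiotensin-converting enzyme, were too dim to be tested. Of the cardiac load markers, MYH7, the slow beta myosin heavy chain, was measured and did not pass: its estimate was 0.61 with angiotensin II (adjusted p = 0.509, limma), with 1.45 and 1.40 in sets 7 and 8 and -0.27 and -0.12 in sets 5 and 6, and -0.70 with losartan (adjusted p = 0.453, limma), with -1.77 in set 2. Probes named NPPA, NPPB, MYH6 or ACTA1 were not found among the named probes. The list of 5 measured load-responsive genes passed in neither arm (camera adjusted p = 0.845 and 0.962). FHL1 had its smallest p in both arms, with estimates of 0.49 with angiotensin II and -0.36 with losartan (limma adjusted p = 0.457 and 0.297). The difference for FHL1 was 0.85 (limma adjusted p = 0.0571). When adjusted over the list alone, 1 member passed with angiotensin II and 0 with losartan. In the difference 2 passed above 0 and 1 below.

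Among named genes past the threshold, the largest fitted positive differences between the effects of angiotensin II and losartan were those of PMCH, the cell cycle genes CCNB1, CDK1 and CCNA2, and the smooth muscle gene CNN1. The difference of the effects, angiotensin II minus losartan, was 3.21 on the log2 scale for CCNB1 (SE 0.42, adjusted p = 0.00707, limma), 2.82 for CDK1 (SE 0.31, adjusted p = 0.00261, limma), 2.66 for CCNA2 (SE 0.31, adjusted p = 0.00370, limma) and 2.51 for CNN1 (SE 0.35, adjusted p = 0.00867, limma). PMCH had a fitted difference of 3.22 (SE 0.51, adjusted p = 0.0179, limma), which is not a measured size, since PMCH was well above background in 0 of 4 losartan fetuses. Its place among the largest differences is therefore not settled. MYLK, another smooth muscle gene, had a difference of 0.16 that did not pass (adjusted p = 0.903, limma). Differences of the opposite sign were found for PLIN5, a coat protein of lipid droplets (-1.05), LPL (-0.999), FGF1 (-0.93) and MYC (-0.83), with limma adjusted p of 0.0211 to 0.0498. They passed in 4 of 21, 5 of 22, 12 of 22 and 7 of 22 alternatives, in that order. Over the alternatives the differences were -1.34 to -0.39 for PLIN5 and -1.73 to -0.50 for LPL. Those of FGF1 were -1.06 to -0.72 and those of MYC -0.99 to -0.72. PLIN5 was well above background on 1 of 4 angiotensin II arrays and in 2 of the 4 untreated twins of the losartan arm.

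Of the lists, that of the cell cycle (12 of 13 differences above 0, median 1.43, camera adjusted p = 1.73e-06; adjusted p = 0.226 with an estimated correlation) and that of the fibroblast and matrix genes (16 of 17, median 0.56, camera adjusted p = 0.0208; adjusted p = 0.464 with an estimated correlation) differed between the treatments. In the cell cycle list 6 genes passed over all tested probes and 9 when adjusted over the list alone. In the matrix list 2 passed, CCN2 (1.49) and TIMP1 (0.65), and 4 when adjusted over the list alone. Without twin sets 2, 7 and 8 the matrix list no longer passed (13 of 17 differences above 0, median 0.13, camera adjusted p = 0.0620), and the cell cycle list did (2.91e-06), though not with an estimated correlation (adjusted p = 0.478) or in fry (adjusted p = 0.174). Without twin set 6 the matrix list did not pass either (camera adjusted p = 0.0646). In fits within a slide, with no twin block and a single losartan array on slide 1 or a single untreated twin of that arm on slide 2, the camera adjusted p was 7.98e-08 and 0.176 for the cell cycle list and 0.0312 and 0.128 for the matrix list.

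In all, 148 of 8970 probes differed between the effects in limma, 117 with a positive and 31 with a negative difference. In the authors' deposited values 1733 did, 790 with a positive and 943 with a negative difference, and 142 of the 148 were among them. The count was 86, 59, 76, 69, 54 and 48 without twin set 1, 3, 4, 6, 7 and 8 in turn, and 3 without the twin set as a block. With the slide as a further block it was 427 and included all 148; within slide 1 it was 38 (32 shared) and within slide 2 1880 (45 shared), in fits that also lacked the twin block. Without twin sets 2, 7 and 8 it was 75, of which 47 were among the 148.

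The estimates of the 2 treatments lay mostly on opposite sides of 0. Across the 564 named genes the log2 changes correlated negatively (Pearson r = -0.449, Spearman rho = -0.527), and 397 genes (70.4%) had estimates of opposite sign. Genes are not independent replicates. No control array was shared, but the 3 arrays apart were an untreated twin of the losartan arm and 2 angiotensin II fetuses. What those arrays have in common enters the 2 effects with opposite signs. Of 64 combinations of label swaps within twin sets, 6, the real one included, gave a correlation as large in size. In fits within a slide, without the twin block, r was -0.204 on slide 1 and -0.653 on slide 2. Of the 109 probes that passed with losartan, 104 (95.4%) had the opposite sign with angiotensin II, and 56 of the 109 had an unadjusted p under 0.05 there. The 89 that fell had a median log2 change of -1.32 with losartan and 0.52 with angiotensin II, and 80 of them passed in the test of the difference. The 20 that rose had medians of 0.85 and -0.20, and 15 passed in the test of the difference. That difference contains the losartan effect by which the 109 probes were chosen. Many could pass it without any effect of angiotensin II, so the counts of 80 and 15 give no support for opposite effects.

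**Figure D4:**
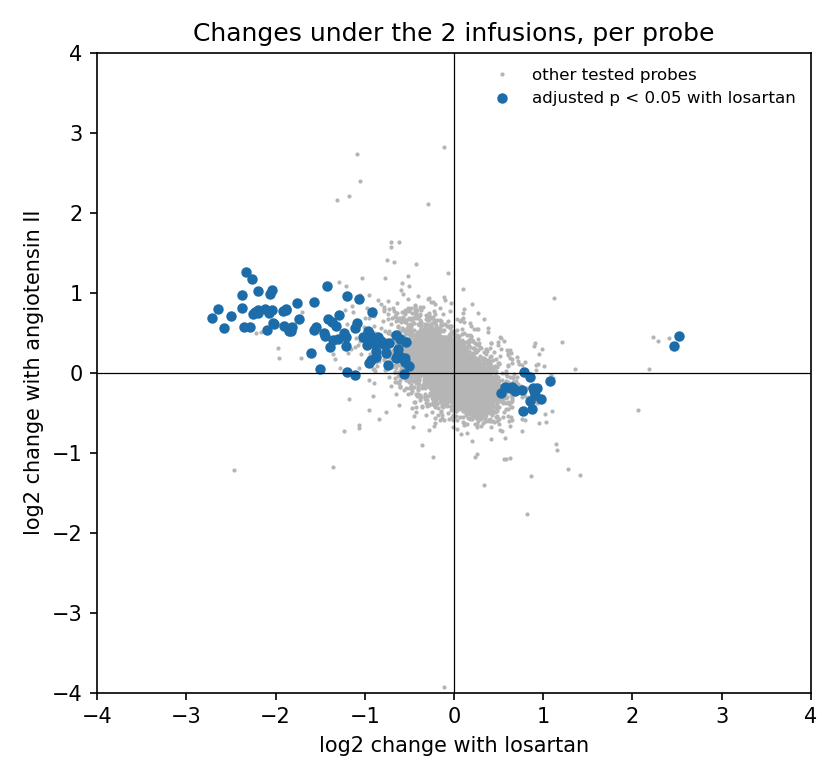
Log2 change with angiotensin II (vertical axis) against log2 change with losartan (horizontal axis) for the 8970 tested probes, with the 109 probes that passed with losartan in blue. Of these, 104 have opposite signs in the 2 arms; the 2 blue points beyond 2 on the horizontal axis are probes of the cathelicidins CATHL3 and CATHL1B.

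No probe passed in the comparison of the untreated twins of the 2 arms. In limma 0 of 8970 passed (smallest adjusted p = 0.208), and 300 had an unadjusted p under 0.05 against 448 expected by chance. Leaving out the untreated twin of set 7 gave 1 passing probe.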

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

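The tests chosen only after the result was seen were those of the slides, the 3 arrays apart, the fibroblast and leukocyte shares, the corner spots and the angiotensin II scores, and all counts of splits except that of the correlation.

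The fall of cell cycle genes with losartan was weighed against the uneven spread of the arm over the slides, the 3 arrays that stood apart and a lower share of fibroblasts. In the fit on twin sets with both fetuses on 1 slide, which for losartan are only sets 2 and 3 and of which set 2 holds an array that stood apart, the list passed (camera adjusted p = 3.12e-06; fry 0.0125; 0.398 with an estimated correlation) while 0 single probes did, and this argues against the slides as the whole cause only as far as those 2 sets and the preset correlation go. Without twin sets 2, 7 and 8 it passed camera (1.10e-06) but neither an estimated correlation (adjusted p = 0.449) nor fry (0.130), and its medians in sets 1, 3 and 4, which hold none of the 3 arrays, were -0.79, -0.62 and -1.40. Its median lay below that of the fibroblast list in 4 of 4 twin sets, by a mean difference of -0.55 (SD 0.38, n = 4). This argues against an even loss of fibroblasts alone. Loss of a dividing part of them could lower the cell cycle list further than the matrix genes, so that stays open. A lower expression of cell cycle genes under AT1 blockade may be the biological explanation and remains a hypothesis, since a change in the share of another dividing cell type was not tested.

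The rise of the cathelicidins CATHL3 and CATHL1B with losartan was weighed against more leukocytes and more blood in the tissue pieces. A several-fold higher share of leukocytes of all kinds would raise their markers alike, and the median of the 8 measured markers was -0.12 (SD 0.22 over the markers), far below the 2.52 of CATHL3. None of these markers is particular to neutrophils, which store cathelicidins, so a rise of neutrophils alone was not tested. Over the 8 untreated hearts CATHL3 did not follow HBB detectably (Pearson r = -0.182, exact permutation p = 0.662, adjusted p = 0.662; Spearman rho = -0.143, exact permutation p = 0.752, adjusted p = 0.752; r = -0.294 without the 2 farthest hearts; 2 relations tested). With 5 of these hearts on slide 1 and 3 on slide 2 there were too few for values within slides. The ratios within twin sets, where the rise was found, were not tested. In losartan sets 1 to 4 they were 0.47, -0.59, 3.30 and 1.42 for HBB. For CATHL3 they were 2.52, 1.31, 3.30 and 2.96, in the same order of size. In angiotensin II sets 5 to 8 they were -1.42, -0.89, 0.15 and -1.70 for HBB, and -0.61, 2.23, 0.61 and -0.41 for CATHL3. More blood, more neutrophils, a narrower class of leukocyte precursors and an effect of losartan therefore stay open. CATHL3 lost its call with the slide as a further block (2.24).

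The 3 arrays apart on the first principal component were the untreated twin of set 2 and the angiotensin II fetuses of sets 7 and 8. Hybridization or washing at neighbouring positions of slide 2 is a candidate explanation: the lowest corner spot signal of the 3 exceeded the highest of the other 13 by 1.74 on the log2 scale. Treatment with angiotensin II as the cause is argued against by the untreated twin of set 2, which scored 47.7 above the lowest angiotensin II array, against an SD of 4.99 over the other 13 arrays. What in the tissue or the assay moved the sheep probes on these arrays was not tested.

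Among 120 groups of 4 values screened, 4 held a value far from the other 3, where chance gives about 1 in 20, or 6. The corner spots of the untreated twin of set 2 had a log2 signal of 17.25, far from those of the other untreated twins of the losartan arm. The log2 75th percentile of the untreated twin of set 1 was 10.10. The interferon-stimulated list had a median log2 ratio of -0.0572 in losartan twin set 2, and CNN1 had a log2 ratio of 2.13 in angiotensin II twin set 6.

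Differences between the effects of the treatments, angiotensin II minus losartan, passed limma's test for 148 probes and camera for the cell cycle list (median 1.43) and the fibroblast and matrix list (0.56). With an estimated correlation neither list passed (adjusted p = 0.226 and 0.464), and without twin sets 2, 7 and 8 the matrix list had a median of 0.13 and did not pass camera (adjusted p = 0.0620). By the rule for named genes these included CCNB1 (3.21), CDK1 (2.82), CCNA2 (2.66), CNN1 (2.51), PLIN5 (-1.05), LPL (-0.999), FGF1 (-0.93) and MYC (-0.83). PMCH had a fitted difference of 3.22, which is not a measured size, as it was well above background in 0 of 4 losartan fetuses.

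Other splits of the samples swapped treated and untreated labels within twin sets. For the difference, 1 of 100 drawn splits, the real one, gave as many as 148 probes, and the highest other gave 0. This argues against chance without an effect of either treatment. An effect of losartan alone could give the same outcome, so the splits do not show that the effects differ. Nor do they separate the treatments from the slides or the 3 arrays apart. The cell cycle list's adjusted p for the difference was 1.73e-06, and 2 of the 100 splits, the real one included, gave one as small (smallest other 1.69e-06). For the 2 lists that differed chance was not excluded, as 32 of 100 splits gave as many and the highest other gave 6. For the correlation of the log2 changes (-0.449) chance was not excluded either: 6 of 64 splits gave a value as large in size, and the highest other was 0.522 in size. Among the untreated twins the real count was 0, so that all 35 splits of the 8 arrays had to give as many, and the count of splits says nothing about chance; the highest other gave 6. Within an arm the 8 splits are too few for a share under 0.05. There the real and highest other values were 109 and 0 probes with losartan (1 of 8 splits as large), 0 and 0 probes with angiotensin II (8 of 8), 2 and 3 lists with losartan (4 of 8) and 1 and 3 lists with angiotensin II (6 of 8).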

How the results depend on the processing

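The alternatives without twin sets 2, 7 and 8 and with slide and array row as blocks were chosen after the results were seen. Among the named genes and lists followed over the alternatives, none that had passed reversed its direction. Reversals were not recorded for the counts of probes. The balance of the probes of the difference did turn in the authors' value table, as given below. Estimates that had not passed did change sign, among them CXCL1 with angiotensin II and with losartan and MYH7 with angiotensin II without twin sets 2, 7 and 8. The fits within a slide had no twin block as well, so those values change 2 choices at once, and in the losartan arm they rest on a single array of 1 group. The cause of the moves was not tested, apart from smaller numbers of arrays, probes or tests where the setting itself has them. Of the values of single genes under the alternatives, 4140 kept their side of the threshold and 242 lost the call. A further 38 gained it and 233 changed sign, passing neither way. Of those of lists 1105 kept their side, 14 lost the call, 31 gained it and 116 changed sign, passing neither way. Most of these values belong to results that had not passed at first, so the counts overstate how well calls held. Among the calls with losartan, TYMS kept its own in 19 of 22 alternatives and CEBPB in 2 of 21. The cell cycle list passed in 23 of 25 alternatives with losartan and in 22 of 25 with angiotensin II, and the matrix list in 23 of 25 with losartan and in 20 of 25 in the difference. The scalings moved the median of all probes by at most 0.05 on the log2 scale. The signal over background limited the genes with dim arrays, and a filter on all 16 arrays gave 58 probes with losartan.

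With losartan 109 probes passed. The count was 434 in the authors' value table (181 higher and 253 lower, 58.3% lower against 81.7%), 0 without the twin set as a replicate block, 68 with it as a random block, 71 with the replicate block plus slide, 0 in twin sets on 1 slide, 42 within slide 1, 546 within slide 2, 166 with array weights, 34 on the 8 arrays of the arm alone, 184 at an adjusted p under 0.1, 309 at an unadjusted p under 0.05 with a fold of 1.5, and 34 over named genes. Leaving out a twin set gave 33 to 99, with 64, 33 and 49 without sets 1, 3 and 4. With angiotensin II the 0 probes became 353 within slide 2, 1 with array row, 1 without twin sets 2, 7 and 8, 168 at an unadjusted p with a fold of 1.5, and 1 over named genes.

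The 148 probes of the difference became 1733 in the authors' value table (790 higher and 943 lower), 3 without the replicate block, 427 with the replicate block plus slide, 0 in twin sets on 1 slide, 38 within slide 1, 1880 within slide 2, 97 with array row, 75 without twin sets 2, 7 and 8, 84 with slide and array row, 347 at an adjusted p under 0.1, 1028 at an unadjusted p with a fold of 1.5, and 33 over named genes. Leaving out a twin set gave 48 to 109. The 0 probes between the untreated twins became 69 at an unadjusted p with a fold of 1.5, and 0 to 1 with 1 array left out (1 without that of set 7).

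For angiotensin II the 1 list became 2 without the replicate block, with it as a random block, with slide or in twin sets on 1 slide, 3 within slide 1, 0 within slide 2, 4 without twin sets 2, 7 and 8, 4 with slide and array row, 0 with an estimated correlation and 3 with the mean of all probes of a gene; fry gave 1, the inflammatory mediators (adjusted p = 0.0177) in place of the cell cycle (0.0708). It was 1 to 3 with a twin set left out. The 2 lists of losartan became 1 within slide 1, 1 within slide 2, 4 without twin sets 2, 7 and 8 and 0 with an estimated correlation. The 2 lists of the difference became 4 with no filter, 1 with the filter on all 16 arrays, 0 within slide 2, 0 with an estimated correlation and 4 by fry, and 1 to 3 with a twin set left out. The correlation of -0.449 became -0.204 within slide 1 and -0.653 within slide 2.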

Other observations

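The tests of PMCH and of the sets left out below were run on patterns noticed in the data; of these, the alternative without twin sets 2, 7 and 8 was chosen after the result was seen.

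Genes induced by interferon had estimates of mostly opposite sign in the 2 arms and did not pass in either. MX1, an antiviral GTPase, had log2 ratios of -1.73, -0.28, -1.31 and -1.55 in losartan twin sets 1 to 4 and 0.75, 2.40, -0.15 and 0.14 in angiotensin II sets 5 to 8. CXCL10, a chemokine induced by interferon, had -2.73, 1.13, -1.10 and -2.44, and 1.54, 2.75, -0.08 and 0.32. Without twin sets 2, 7 and 8 the list of 6 interferon-stimulated genes passed camera with losartan (median -0.68, adjusted p = 0.00598) and with angiotensin II (1.17, adjusted p = 1.63e-06). With an estimated correlation neither passed (adjusted p = 0.703 and 0.57), nor did fry (0.224 and 0.588). The list medians of the left-out sets 2, 7 and 8 were -0.06, -0.25 and -0.004, so leaving these sets out favoured a pass. For angiotensin II that fit rests on sets 5 and 6 alone, with list medians of 0.49 and 1.87. The camera results without these sets are therefore no separate support for an interferon effect. Several estimates under angiotensin II came from sets 7 and 8: without sets 2, 7 and 8 that of CXCL1 went from 1.64 to -0.16, that of MYH7 from 0.61 to -0.20 and that of COL4A1, a collagen chosen after its values were seen, from 0.78 to -0.20.

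ASIP, the agouti signalling protein of coat colour, was chosen after its values were seen. Both of its probes were not well above background in the untreated twin of set 8 (-5.57 and -5.79 on the normalized log2 scale), while both were on the other 15 arrays. The angiotensin II twin of set 8 had 3.49 and 0.41. As the untreated twin was not measured above background, no ratio is given for that set, and neither probe passed with angiotensin II in limma (adjusted p = 0.466 and 0.459). No explanation was tested.

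PMCH, a hormone precursor of the hypothalamus, fell with losartan, and its gene neighbours PARPBP in the reference gene table. One hypothesis was that its probe may read a transcript that follows the cell cycle. Over the 8 untreated hearts, in 7 of which it was well above background, PMCH correlated with the median of the cell cycle list at a Pearson r of 0.919 (exact permutation p = 0.0510, adjusted p = 0.102) and a Spearman rho of 0.50 (exact permutation p = 0.216, adjusted p = 0.432; 2 relations tested). Without the 2 hearts farthest from the median r was 0.276, so the relation rests on those hearts, and the hypothesis stays open.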
